A study of Rattus norvegicus with 36 samples.

How the data were processed

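Liver RNA from 36 male Harlan Sprague Dawley rats was measured on 36 single-colour Affymetrix rat expression arrays, 1 per animal. Per the labels' protocols, the animals were 7 weeks old at the start, were dosed by gavage in corn oil on 5 consecutive days, and were necropsied 1 day after the last dose. RNA from the left lobe was amplified and labelled with biotin with the 3' IVT Plus kit after a check of concentration, purity and RNA integrity, per the labels' protocols. The RNA integrity values of single samples are not given in the sources used here.

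The deposited values are log2 expression values per probe set that the authors made with RMA (background correction, quantile normalization and median polish over probes) from the affy package, per the submitters' processing notes. The versions of RMA and affy are not given in the sources used here. The log2 scale was checked on the values, which lie between 1.43 and 14.43 in all 36 arrays with array medians from 4.59 to 4.66. Per the series' design text, the authors compared each dose with vehicle in R/maanova at a false discovery rate under 5%. That test was replaced here by limma, and no result of it was used.

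The 57 array control probe sets were left out and 31042 probe sets were tested without a filter on signal. The probe table pairs 20826 of them with 1 gene and 436 with several, and 9780 have no gene in it. These pairs cover 14217 genes. Symbols were checked through Entrez identifiers against a table of rat genes, in which 20758 probe sets with 1 gene matched and 0 symbols had to be updated. A gene is represented by the probe set with the highest mean over the 36 arrays among those naming exactly 1 gene.

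All 36 arrays entered 1 linear model with a mean per group (R 4.3.3, limma 3.58.1, lmFit, contrasts.fit and eBayes without a variance trend). Each dose was compared with vehicle, and 943 with 94.3 mg/kg. A moderated F test covered the 5 dose coefficients, and a second model fitted a slope over the dose rank from 0 to 5. P values are two-sided and were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Standard errors and 95% intervals come from the moderated model. For arrays, the number of animals limits the precision: the residual SD had a median of 0.139 over the genes.

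Gene lists were tested with camera on the moderated statistics of 1 probe set per gene, with a preset correlation of 0.01, beside camera with an estimated correlation and fry. The 29 lists hold 549 different genes, of which 472 were measured, and all 29 had at least 5 measured genes. They are CAR and PXR targets, aryl hydrocarbon receptor targets, PPARalpha and fatty acid oxidation, NRF2 and oxidative stress, cholesterol synthesis, fatty acid and triglyceride synthesis, bile acid synthesis and transport, thyroid hormone response and metabolism, p53 and DNA damage, cell cycle, ER stress and ATF4, heat shock, acute phase, interferon response, circadian clock, gluconeogenesis and fasting, urea cycle and amino acids, male-predominant and female-predominant liver genes, and markers of hepatocytes, Kupffer cells and macrophages, stellate cells and fibroblasts, endothelium, cholangiocytes, lymphocytes, neutrophils, erythroid cells, pancreatic acini, and adipose and muscle. List p values were adjusted over the 29 lists within a comparison. Members were also adjusted over the list alone.

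Named genes follow a rule. Up to 15 genes per direction with the largest change among those that passed at a dose, and up to 5 among those that passed between 943 and 94.3 mg/kg, were to be named, and 0 passed. At each dose where fewer than 5 genes passed, which was every dose, the 3 genes with the smallest p in each direction are named as not passing. Up to 4 members of a list with the smallest p at the dose described, all measured genes among 26 chosen response genes at 943 mg/kg, and up to 10 genes with the smallest p of the trend complete it. Of the 26, 20 had a probe set naming 1 gene. Entries without a proper symbol were left out of the text and kept in the counts. Where another probe set of a gene had the opposite sign, the text says so.

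The groups, comparisons, tests, lists, named-gene rule and all alternatives but 3 were fixed before the data were examined. The alternatives fixed then were the upper 50% of probe sets by mean, a variance trend with robust estimation, array weights, the replicate number as a block, quantile normalization again, centring on array medians, an unmoderated linear model, 1 probe set per gene, a fit of 2 groups only, adjustment over all 5 doses, a minimum of 1.5-fold, other dose scores for the trend, a trend without the highest dose, other list tests, leaving out each animal in turn, and leaving out the array with the lowest median correlation with the others. Added after seeing the data were an exact permutation of the 12 animals on each list mean, a clock gene covariate for the cholesterol synthesis list, and leaving out each animal for the values of single genes and that list. The labels do not say that equal replicate numbers pair animals, so no pairing was used.

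For other groupings of the animals, 100 splits per comparison, the real one included, were fitted in the same way. Shared vehicle arrays were addressed with 100 simulated draws of unchanged groups. The scripts were tested on simulated data with the spread of the real arrays and 50 probe sets changed per fold size among 31042. For 943 mg/kg against vehicle, the test recovered 52% of probe sets changed 1.25-fold, 94% of those changed 1.5-fold and 100% of those changed 2-fold. For 94.3 mg/kg these shares were 50%, 98% and 100%, for 9.4 mg/kg 56%, 92% and 100%, for 0.94 mg/kg 56%, 90% and 98%, and for 0.1 mg/kg 50%, 94% and 100%. All fold sizes were present at once, which eases the adjusted threshold, and the noise was drawn independently per probe set. A lone change in the real arrays would be recovered less often, so these shares do not say what 0 calls exclude.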

Results

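Gene expression was measured in the liver of 36 male Harlan Sprague Dawley rats that received tetrabromobisphenol A-bis(2,3-dibromopropyl ether), a brominated flame retardant abbreviated TBBPA-DBPE, or corn oil alone by gavage on 5 consecutive days. The 6 groups were vehicle (0 mg/kg) and doses of 0.1 mg/kg, 0.94 mg/kg, 9.4 mg/kg, 94.3 mg/kg and 943 mg/kg, with 6 animals and 1 array per animal in each group. Each array gave log2 expression values, of which 31042 probe sets were tested after 57 array control probe sets had been left out. Array medians lay between 4.59 and 4.66 on the log2 scale and the values between 1.43 and 14.43. The correlation of any 2 arrays over the probe sets lay between 0.989 and 0.997. Its median was 0.994 for pairs within a group and 0.994 for pairs from different groups. The first principal component held 9.81% of the variance and the second 7.66%. Differences below are log2 values of dose minus vehicle with the SE of the limma fit and n = 6 animals per group, and every adjusted p for a gene comes from limma. The number of arrays limits the precision, with a median SE of 0.0831 over the probe sets.

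The first question was whether any dose altered the hepatic transcriptome against vehicle. No gene passed the adjusted threshold in limma at any dose. The counts at an unadjusted p under 0.05 were 1744 probe sets at 0.1 mg/kg, 1292 at 0.94, 1506 at 9.4, 2142 at 94.3 and 1782 at 943 mg/kg, beside 1552.1 that chance gives. Of these, 932, 653, 685, 1142 and 954 were higher than in vehicle. The smallest adjusted p per dose was 0.689, 0.999, 0.750, 0.331 and 0.865 in ascending order of dose. An ordinary linear model without moderation, the other tool run at this level, also gave 0 probe sets at each dose. The 95% interval of the difference excluded a 2-fold change for 99.6%, 99.7%, 99.6%, 99.5% and 99.6% of the probe sets in the same order, and a 1.5-fold change for 98.1%, 98.2%, 97.8%, 97.6% and 97.9%. These shares include dim probe sets, which were not filtered out and cannot show small changes, so they describe measured values only. Measured differences of 2-fold or more were seen for 4, 4, 5, 8 and 7 probe sets. Some of these probe sets had widely separated high and low values among animals, so the group mean hung on few animals. Among them were those of Ugt2b at 0.1 and 943 mg/kg, Ephx2 at 943 mg/kg, and some without a gene name at 0.94, 9.4 and 94.3 mg/kg.

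**Figure D1:**
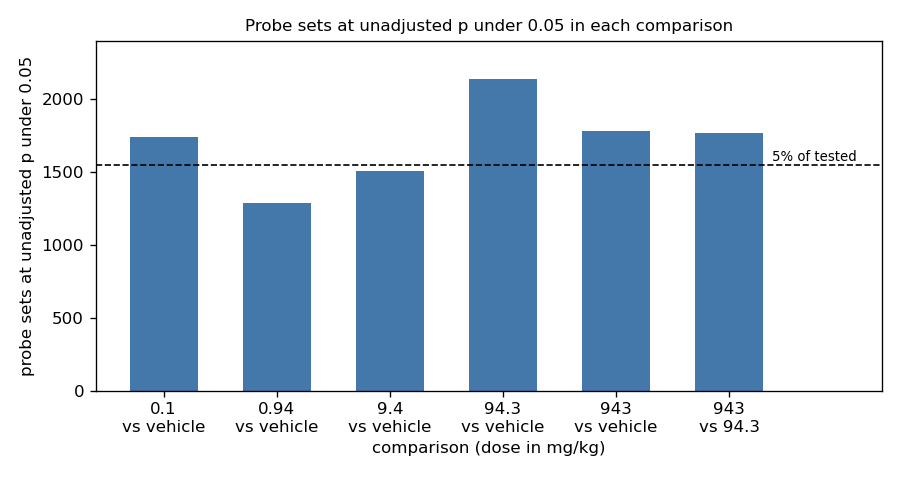
Number of probe sets with an unadjusted p under 0.05 (bars) in each comparison of a dose in mg/kg with vehicle and of the 2 highest doses, with a dashed line at 5% of the 31042 tested. The counts against vehicle run from 1292 at 0.94 mg/kg to 2142 at 94.3 mg/kg, and the dashed line lies at 1552.1.

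At 943 mg/kg, Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was 1.27-fold above vehicle (3.88 ± 0.16 in vehicle and 4.22 ± 0.21 at 943 mg/kg, SD, n = 6). Both means lay below every array median, so that the size of this fold is uncertain. Of the 6 animals, 5 lay above the highest vehicle animal. The log2 difference was 0.34 ± 0.078 (SE) and did not pass the test over all probe sets (adjusted p = 0.865). Cyp1a1 was the 1 member of the aryl hydrocarbon receptor target list that passed in the upward direction when adjusted over the list alone (adjusted p = 0.000799). Such an adjustment does not cover the 29 lists or the 6 comparisons, so some calls can arise by chance. It gave 4, 0, 1, 6 and 2 calls over all lists from the lowest to the highest dose, and 6 between the 2 highest doses. Cyp1a2, another receptor target and an abundant hepatic P450, differed by 0.08 with a 95% interval from -0.06 to 0.22. Dnajc15, a mitochondrial co-chaperone, was higher by 0.27 ± 0.058 in 6 of 6 animals above the vehicle range, and Rad9b, a paralogue of the checkpoint protein Rad9, by 0.38 ± 0.093. Cnst, which encodes the connexin trafficking protein consortin, was lower by a log2 difference of -0.33 ± 0.078 in 6 of 6 animals below the vehicle range, Tekt4 by -0.33 ± 0.082 and Tnrc6b by -0.29 ± 0.075. All 5 of these genes had the same adjusted p of 0.865. The 2 other probe sets of Cnst differed by -0.01 and -0.07, and the 2 of Tnrc6b by -0.21 and -0.10. The vehicle signals of Rad9b (3.05) and Tekt4 (3.13) lay below every array median, so the size of their differences is uncertain.

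The other response genes chosen in advance were read at 943 mg/kg. Cyp3a23-3a1 and Cyp3a2, which respond to the pregnane X receptor, differed by -0.04 (95% interval -0.21 to 0.13) and -0.02 (-0.11 to 0.07). Cyp4a1, a target of PPARalpha, differed by -0.24 (-0.56 to 0.09). Nqo1 and Hmox1, targets of NRF2, differed by 0.12 and -0.19. The glucuronosyltransferase Ugt2b1 differed by -0.28 (-0.54 to -0.02), the transporter Abcc3 by -0.12, the P450 reductase Por by 0.05, and the deiodinase Dio1 by -0.0054. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.13 with an SE of 0.413 and a 95% interval from -0.97 to 0.71. Lipogenic genes varied among animals, with Fasn at 0.34 ± 0.21, Scd at -0.56 ± 0.37, Thrsp at 0.26 ± 0.31 and the sterol enzyme Sqle at 0.46 ± 0.24. The p53 targets Cdkn1a and Mdm2 differed by -0.16 and -0.08, the proliferation marker Mki67 by 0.07 and the stress factor Ddit3 by -0.09. Another probe set of Cdkn1a had the opposite sign. Many of these values moved toward or past 0 by over 1.5 times when 1 animal was left out. Abcc3 was at -0.04 and Mdm2 at 0.0088 without vehicle replicate 1, Cyp7a1 at 0.07 and Mki67 at -0.02 without replicate 3, and Fasn at 0.19 and Thrsp at 0.05 without replicate 4. Without vehicle replicate 5, Scd was at -0.26, Cdkn1a at -0.0070 and Ddit3 at -0.0066. In the group at 943 mg/kg, Sqle was at 0.30 and Por at -0.05 without replicate 1, Dio1 at 0.04 without replicate 2, Cyp3a2 at -0.0049 without replicate 4, and Nqo1 at 0.05 and Cyp3a23-3a1 at -0.0040 without replicate 6. None of these genes passed the test, with adjusted p from 0.865 to 0.994. The vehicle signals of Abcc3 (4.20) and Mki67 (3.36) lay below every array median, so the size of their differences is uncertain. Cyp2b1, Cyp2b2, Gsta2 and Ugt1a1 were represented only by probe sets that name several genes and have no value here.

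**Figure D2:**
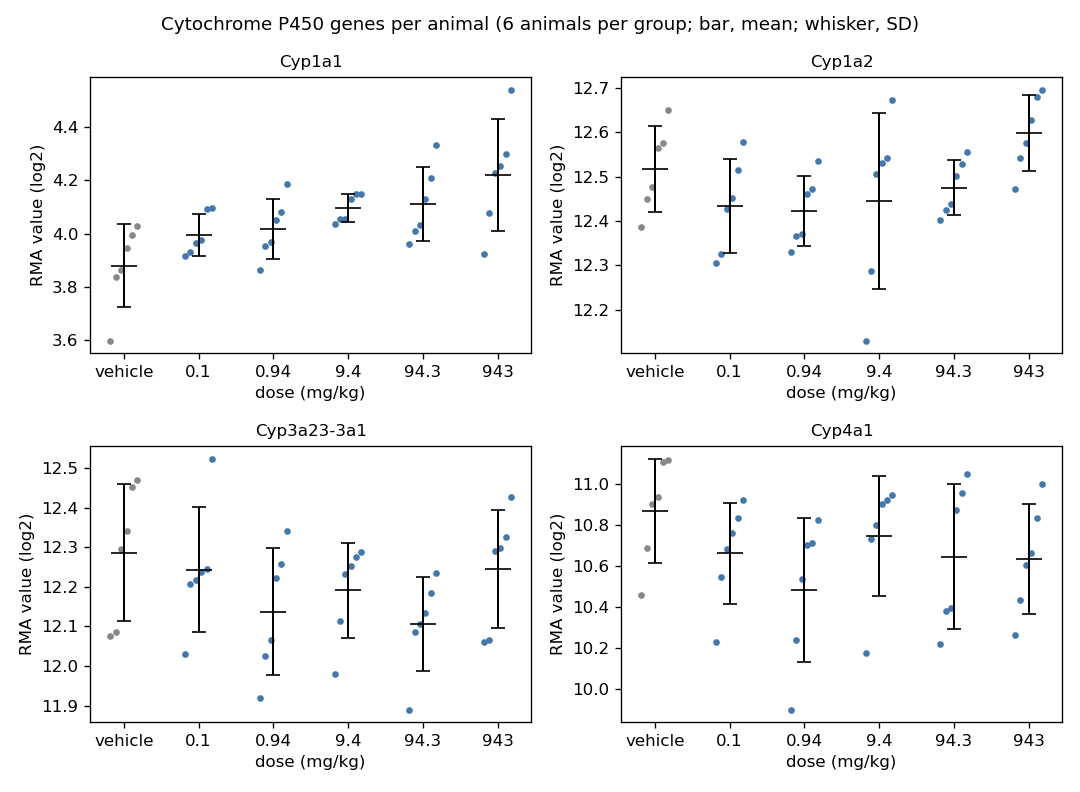
Log2 expression of Cyp1a1, Cyp1a2, Cyp3a23-3a1 and Cyp4a1 per animal by dose in mg/kg, with points for the 6 animals of a group, a bar at the mean and whiskers of 1 SD. The Cyp1a1 mean is 3.88 in vehicle and 4.22 at 943 mg/kg, with 5 of 6 animals above the vehicle range.

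Among the 29 gene lists, cholesterol synthesis stood out at 943 mg/kg. Of its 20 measured members, 19 were higher than in vehicle, with a median log2 difference of 0.32. The mevalonate pathway enzymes Pmvk, Mvk and Fdps differed by 0.35 ± 0.13, 0.36 ± 0.14 and 0.31 ± 0.12, and Msmo1, a later sterol enzyme, by 0.44 ± 0.19. No member passed, either over all probe sets or adjusted over the list alone. The list was past the threshold of camera with a preset correlation (adjusted p = 1.36e-07) and lost the call when the correlation was estimated from the animals (adjusted p = 0.819 with an estimated correlation). An exact permutation of the 12 animals on the list mean, a test chosen after seeing the data, gave p = 0.126, with 4 of 6 animals above the vehicle range. The mean difference of the list was 0.27, and 0.17 without replicate 1 at 943 mg/kg.

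With all animals, no other metabolic or stress list passed at 943 mg/kg, where camera with the preset correlation gave the following medians. The cell cycle list had 0.09 (adjusted p = 0.0801), bile acid synthesis and transport -0.06 (0.111), heat shock -0.05 (0.164), acute phase -0.03 (0.164), and urea cycle and amino acid metabolism -0.03 (0.164). PPARalpha and fatty acid oxidation genes had -0.04 (0.217), male-predominant genes -0.07 (0.217), interferon response -0.12 (0.238), CAR and PXR targets -0.03 (0.238), circadian clock -0.07 (0.244), and aryl hydrocarbon receptor targets 0.04 (0.311). NRF2 targets had -0.0041 (0.459), fatty acid and triglyceride synthesis 0.08 (0.485), p53 targets 0.01 (0.543), and gluconeogenesis and fasting genes -0.0058 (0.587). Female-predominant genes had 0.04 (0.690), ER stress and ATF4 targets -0.02 (0.797), and thyroid hormone response 0.0058 (0.869). The mean differed in sign from the median for the female-predominant list (-0.01) and the ER stress list (0.03), while the thyroid list had a positive mean and a downward test. Among their members, Sds, serine dehydratase, was at -0.50 ± 0.20, the chaperone Hsph1 at -0.43 ± 0.14, and the p53 target Sesn1 at 0.28 ± 0.092. With 1 animal left out, 7 lists passed camera at 943 mg/kg without vehicle replicate 5, 4 without vehicle replicate 1 or without replicate 1 or 3 of the dose group, and 2 without vehicle replicate 2 or 4 or without replicate 2 or 6 of the dose group.

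With all animals, no list of cell type markers passed camera at 943 mg/kg. The median was -0.00094 for hepatocyte markers (adjusted p = 0.587), -0.07 for Kupffer cell and macrophage markers (0.393), -0.04 for endothelial markers (0.244), 0.02 for stellate cell and fibroblast markers (0.587), and 0.0072 for cholangiocyte markers (0.854). Lymphocyte markers had 0.05 (0.640), neutrophil markers 0.21 (0.355), erythroid markers 0.0020 (0.877), pancreatic acinar markers -0.03 (0.587), and adipose and muscle markers -0.02 (0.869). The neutrophil list mean lay above the vehicle mean in 6 of 6 animals and above the vehicle range in 3, with an exact permutation p = 0.0346 and an adjusted p of 0.803 over the 29 lists. In vehicle, the means of the neutrophil (3.75), pancreatic acinar (3.84) and adipose and muscle (4.02) lists lay below every array median. The size of their differences is uncertain. The cholangiocyte and adipose lists had means of the opposite sign (-0.0014 and 0.04), and the cholangiocyte and erythroid lists had downward tests. Ptprb, an endothelial receptor phosphatase, was lower by -0.25 ± 0.076 and passed when adjusted over the list alone (adjusted p = 0.0267), not over all probe sets. Its differences at 0.1 mg/kg (-0.24, adjusted over the list alone 0.0403) and at 94.3 mg/kg (-0.29, adjusted over the list alone 0.00576) use the same 6 vehicle arrays and are not independent repeats. Unchanged groups set against shared vehicle arrays gave a mean r of 0.484 for 0.1 with 943 mg/kg and 0.497 for 94.3 with 943 mg/kg over the probe sets in 100 simulated draws.

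At 94.3 mg/kg, Psph, the last enzyme of serine synthesis, was among the genes with the smallest p and lay above vehicle by 0.58 ± 0.12, with 5 of 6 animals above the vehicle range. Psat1 and Phgdh, the preceding enzymes of that route, differed by 1.09 ± 0.25 (2.12-fold) and 0.79 ± 0.24. Psat1 also lay above the same vehicle arrays by 0.93 at 0.1 mg/kg and 0.45 at 0.94 mg/kg. Its trend over dose rank did not pass (limma adjusted p = 0.877). Asns, asparagine synthetase, differed by 0.98 ± 0.26 (1.97-fold), and Slc7a11, the cystine importer, by 1.03 ± 0.25. Without replicate 5 at 94.3 mg/kg, the Slc7a11 difference was 0.71. The Slc7a11 signal in vehicle, 3.59, lay below every array median, so that the size of its differences is uncertain. Limk2, an actin-regulating kinase, was higher by 0.45 ± 0.095, and the deubiquitinase Otub2 by 0.81 ± 0.17 (1.75-fold). Sash1, a scaffold protein, was lower by -0.54 ± 0.13, Mysm1, a histone deubiquitinase, by -0.38 ± 0.097 in 6 of 6 animals below the vehicle range, and Tekt4 by -0.36 ± 0.082. These genes did not pass over all probe sets, with a smallest adjusted p of 0.331. Another probe set of Mysm1 differed by -0.08. Adjusted over the list alone, Psat1 and Asns and Phgdh passed in the ER stress and ATF4 list (smallest adjusted p = 0.00352), Slc7a11 in the NRF2 list (0.00607) and Cyp1a1 in the aryl hydrocarbon receptor list (0.0402).

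**Figure D3:**
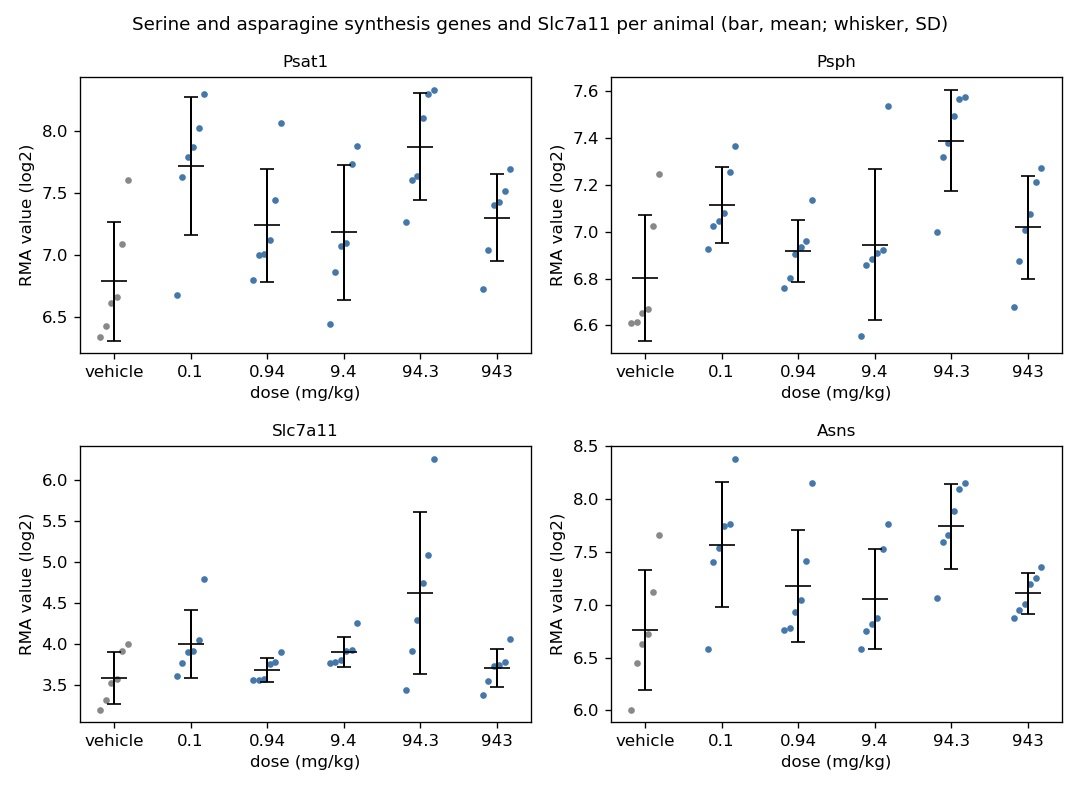
Log2 expression of Psat1, Psph, Slc7a11 and Asns per animal by dose in mg/kg, with points for the 6 animals of a group, a bar at the mean and whiskers of 1 SD. Psat1 differs from vehicle by 0.93 at 0.1 mg/kg, 0.45 at 0.94 mg/kg, 1.09 at 94.3 mg/kg and 0.51 at 943 mg/kg. At 9.4 mg/kg its difference lies between 0.25 and 0.56 with 1 animal left out. All these differences use the same vehicle arrays.

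The count at 94.3 mg/kg depended on 1 animal. Without replicate 1 of that dose group, 11 probe sets passed in limma (10 higher and 1 lower, smallest adjusted p = 0.0368). Of 12 runs with 1 animal left out, this was the 1 with any call, so the animal was picked by its outcome. Among 100 splits of all 12 animals, 5 gave a call, with at most 4 probe sets. The higher ones were Limk2, Otub2, Psph, Slc7a11 (log2 1.27), Slc3a2, Yars1, Wdr12, Rrp12, Apex1 and Ndufaf4, and the lower one has no gene name. Slc3a2, Yars1, Wdr12, Rrp12, Apex1 and Ndufaf4 lie outside the rule for named genes and were singled out after their values were seen.

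Of the 29 lists, 6 passed camera with the preset correlation at 94.3 mg/kg, each with the call lost when the correlation was estimated. Cholesterol synthesis genes were higher in 19 of 20 members with a median of 0.27 (adjusted p = 1.05e-06, and adjusted p = 0.436 with an estimated correlation). Mvd differed by 0.64 ± 0.22, Sqle by 0.68 ± 0.24, Msmo1 by 0.52 ± 0.19 and Fdps by 0.35 ± 0.12. Heat shock genes were higher in 14 of 16 members with a median of 0.09 (0.00231, and adjusted p = 0.436 with an estimated correlation), with Hspb8 at 0.26, Fkbp4 at 0.23 and Bag3 at 0.21. Fatty acid and triglyceride synthesis genes were higher in 15 of 21 members with a median of 0.14 (0.0134, and adjusted p = 0.436 with an estimated correlation), with Pnpla3 at 0.87, Elovl6 at 0.51 and Gpam at 0.36. Cell cycle genes were higher in 35 of 39 members with a median of 0.08 (0.0310, and adjusted p = 0.746 with an estimated correlation). Male-predominant genes were higher in 0 of 8 members with a median of -0.13 (0.0132, and adjusted p = 0.436 with an estimated correlation), with Stac3 at -0.62 and Cyp2a2 at -0.10. PPARalpha genes had a median of -0.04 and were higher in 8 of 35 members (0.0134, and adjusted p = 0.718 with an estimated correlation), with Pdk4 at -0.64 and Angptl4 at -0.61. Gluconeogenesis and fasting genes, a list that did not pass camera (median -0.11, adjusted p = 0.138), had the smallest exact permutation p of the dose (0.00216, the smallest possible, and 0.0628 after adjustment over the 29 lists, so that a lone list could not pass), with the serine dehydratase Sds at -0.43. With 1 of the 12 animals left out in turn, cholesterol synthesis passed camera in 12 of 12 runs, heat shock in 11 (adjusted p = 0.0774 without replicate 3 at this dose), male-predominant genes in 10 (up to 0.0589 without replicate 3), PPARalpha genes in 8 (lost without vehicle replicates 4 and 5 and without replicates 1 and 2 at this dose), fatty acid and triglyceride synthesis in 7 (up to 0.201 without vehicle replicate 4) and cell cycle in 6 (up to 0.487 without replicate 6). Without replicate 3 at 94.3 mg/kg Stac3 was at -0.31, and without replicate 5 Elovl6 was at 0.32. The mean difference of the cholesterol list was 0.28, and 0.18 without replicate 3 at 94.3 mg/kg.

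**Figure D4:**
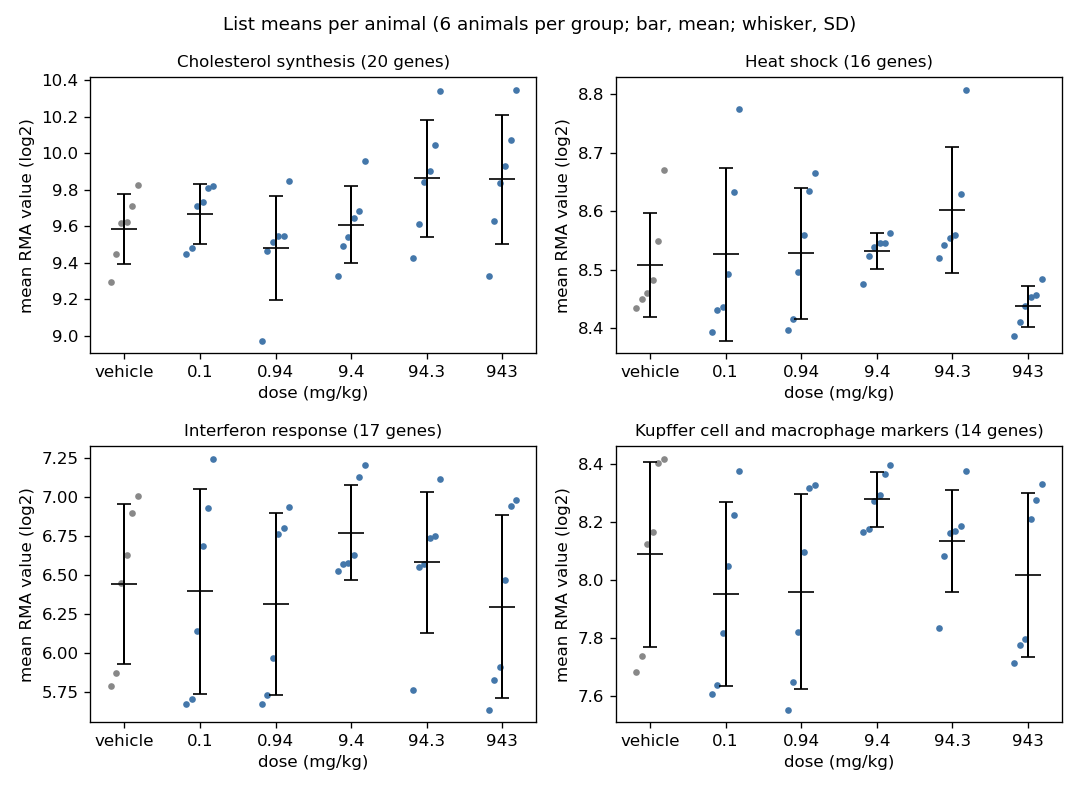
Mean log2 expression of the cholesterol synthesis, heat shock, interferon response and Kupffer cell and macrophage lists per animal by dose in mg/kg, with points for the 6 animals of a group, a bar at the mean and whiskers of 1 SD. The cholesterol synthesis mean is 9.59 in vehicle, 9.86 at 94.3 mg/kg and 9.86 at 943 mg/kg.

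At 9.4 mg/kg, the gene with the smallest p was Slco4a1, an organic anion transporter, which was higher by 0.36 ± 0.073 in 6 of 6 animals above the vehicle range (adjusted p = 0.750). Siva1, an apoptosis regulator, differed by 0.23 ± 0.058 and Dph7, of diphthamide synthesis, by 0.24 ± 0.063. The other probe sets of Slco4a1 and Siva1 differed by 0.02 and 0.08. Lower values were found for Cep135, a centriole protein (-0.40 ± 0.097), Klk1c8 (-0.28 ± 0.070) and the helicase Ddx31 (-0.31 ± 0.081), all with an adjusted p of 0.980. The vehicle signals of Slco4a1 (3.94), Cep135 (4.19) and Klk1c8 (2.76) lay below every array median, so the size of their differences is uncertain. Without replicate 3 of that dose group, 1 probe set passed, that of Cep135 (-0.50, adjusted p = 0.0457). Of 12 runs with 1 animal left out, this was the 1 with any call. Acacb, which makes malonyl-CoA at mitochondria, passed when adjusted over the list alone (-0.34, adjusted p = 0.0319).

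Immune and proliferation lists led at 9.4 mg/kg, where 7 lists passed camera with the preset correlation. Cell cycle genes were higher in 32 of 39 members with a median of 0.14 (adjusted p = 0.0001, and adjusted p = 0.582 with an estimated correlation), among them Aurkb at 0.38, Mki67 at 0.37, Birc5 at 0.25 and Pcna at 0.13. Interferon response genes were higher in 16 of 17 members with a median of 0.33 (0.00859, and adjusted p = 0.647 with an estimated correlation), with Mx1 at 0.54 and Cxcl10 at 0.53. Kupffer cell and macrophage markers were higher in 13 of 14 members with a median of 0.20 (0.0102, and adjusted p = 0.647 with an estimated correlation), with Adgre1 at 0.39. Lymphocyte markers were higher in 13 of 17 members with a median of 0.14 (0.0109, and adjusted p = 0.582 with an estimated correlation), with Gzmb at 0.33, Ptprc at 0.35 and Cd3e at 0.21, of which another Cd3e probe set had the opposite sign. Neutrophil markers were higher in 6 of 7 members with a median of 0.16 (0.0203, and adjusted p = 0.573 with an estimated correlation), with S100a9 at 0.57. Urea cycle genes were higher in 2 of 17 members with a median of -0.04 (0.0277, and adjusted p = 0.582 with an estimated correlation). Bile acid genes were higher in 5 of 20 members with a median of -0.04 (0.0294, and adjusted p = 0.573 with an estimated correlation), with Cyp8b1 at -0.25. The interferon list mean fell into 2 separate ranges over the 36 animals, and the lower range held 2 of the 6 vehicle animals and 0 of the 6 animals at 9.4 mg/kg. With 1 of the 12 animals left out in turn, cell cycle passed camera in 11 of 12 runs (adjusted p = 0.0794 without replicate 4 at this dose), Kupffer cell markers in 10 (up to 0.262 without vehicle replicate 5), interferon response in 8 and lymphocyte markers in 8 (up to 0.159 and 0.133 without vehicle replicate 1), and urea cycle and bile acid genes in 6 each (up to 0.182 and 0.217 without replicate 4). Neutrophil markers passed in 9, and without replicate 1 at 9.4 mg/kg, whose list mean was 4.78 beside 3.88 in the next animal, their adjusted p was 0.399 and S100a9 was at 0.24. Without replicate 4 at 9.4 mg/kg Aurkb was at 0.19 and Cxcl10 at 0.31, and without vehicle replicate 1 Mx1 was at 0.31, Adgre1 at 0.24 and Ptprc at 0.23.

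At 0.94 mg/kg, the smallest p in the upward direction belonged to Taf1d (0.32 ± 0.080), Rbak (0.31 ± 0.077) and Nek4 (0.41 ± 0.11), and another probe set of Taf1d had the opposite sign. Fes, a tyrosine kinase, differed by -0.34 ± 0.089, the zinc exporter Slc30a1 by -0.36 ± 0.10 and the lipoxygenase Alox12 by -0.28 ± 0.081. None passed, with a smallest adjusted p of 0.999. Another probe set of Nek4 differed by 0.09. The vehicle signals of Rbak (4.26), Nek4 (4.24) and Alox12 (3.20) lay below every array median, so the size of their differences is uncertain. Of the lists, 6 passed camera with the preset correlation. PPARalpha and fatty acid oxidation genes were lower in all but 8 of 35 members with a median of -0.09 (adjusted p = 0.000133, and adjusted p = 0.882 with an estimated correlation), with Cyp4a1 at -0.38, Pex11a at -0.29, Ehhadh at -0.27 and Cd36 at -0.25. Cholesterol synthesis (-0.09, adjusted p = 0.0385), Kupffer cell markers (-0.13, 0.0385), urea cycle genes (-0.05, 0.0385) and lymphocyte markers (-0.09, 0.0402) had negative medians, and ER stress and ATF4 targets a positive one (0.06, 0.0402). All 6 lost the call (adjusted p = 0.882 with an estimated correlation). The mean difference of the cholesterol list was -0.10, and -0.0022 without replicate 2 at 0.94 mg/kg, where its adjusted p was 0.732. Without that animal Cd36 was at -0.12, and without vehicle replicate 4 Pex11a was at -0.16. With 1 of the 12 animals left out in turn, PPARalpha genes passed camera in 11 of 12 runs (0.0658 without vehicle replicate 4), cholesterol synthesis in 6, Kupffer cell and lymphocyte markers in 5 each (up to 0.481 without vehicle replicate 2), urea cycle genes in 4 (up to 0.261 without replicate 2 at this dose) and ER stress targets in 3 (up to 0.431 without vehicle replicate 4). The Kupffer cell markers divided the animals into the same 2 ranges as the interferon list, and the lower range held 3 of 6 animals at 0.94 mg/kg beside 2 of 6 in vehicle.

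At 0.1 mg/kg, Ccl28, a mucosal chemokine, was higher by 0.34 ± 0.076 in 6 of 6 animals above the vehicle range, Mcrip2 by 0.33 ± 0.082 and Psat1 by 0.93 ± 0.25 (1.90-fold). Lower values were found for the phosphatase Lhpp (-0.22 ± 0.054), Alox12 (-0.31 ± 0.081) and the anion transporter Slc22a8 (-0.21 ± 0.057). The smallest adjusted p was 0.689. The vehicle signals of Ccl28 (4.15) and Alox12 (3.20) lay below every array median, so the size of their differences is uncertain. Adjusted over the list alone, Aldh3a1 (-0.31, adjusted p = 0.00722) and Psat1 with Asns (smallest adjusted p = 0.0211) passed. Camera with the preset correlation passed 7 lists. Urea cycle and amino acid genes had a median of -0.08 with Sds at -0.58 and Slc25a13 at -0.19 (adjusted p = 0.000456, and adjusted p = 0.321 with an estimated correlation). Bile acid genes had -0.04 (0.0402) and gluconeogenesis and fasting genes -0.12 (0.0420), with Pck1, the gluconeogenic carboxykinase, at -0.43 (adjusted p = 0.321 with an estimated correlation for both). PPARalpha genes had -0.05 (0.0402), Kupffer cell markers -0.13 (0.0402) and cell cycle genes 0.07 (0.0420), each with adjusted p = 0.878 with an estimated correlation. Male-predominant genes had -0.11 (0.0420, and adjusted p = 0.612 with an estimated correlation), with the steroid dehydrogenase Hsd3b5 at -0.19. With 1 of the 12 animals left out in turn, urea cycle genes passed camera in 12 of 12 runs, PPARalpha genes in 8 (adjusted p up to 0.652 without vehicle replicate 4), bile acid genes in 6 (up to 0.141 without replicate 6 at this dose), cell cycle in 6 (up to 0.527 without vehicle replicate 6), Kupffer cell markers in 5 (up to 0.412 without vehicle replicate 2), gluconeogenesis in 4 (up to 0.161 without replicate 6) and male-predominant genes in 4 (up to 0.182 without vehicle replicate 3). Without replicate 2 at 0.1 mg/kg Pck1 was at -0.24. The lower of the 2 ranges of the Kupffer cell markers held 3 of 6 animals at 0.1 mg/kg beside 2 of 6 in vehicle.

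The next question was whether expression followed the dose. Tekt4, a tektin of ciliary microtubules with a low signal in liver (3.13 in vehicle), had the smallest p, with a slope of -0.08 per dose rank (adjusted p = 0.116). Cnst followed with -0.06 (adjusted p = 0.219) and Cyp1a1 with 0.06 (adjusted p = 0.231). The Cyp1a1 difference from vehicle was 0.12, 0.14, 0.22, 0.23 and 0.34 from the lowest to the highest dose, 5 values that share the same vehicle arrays. Without vehicle replicate 1, the first 2 were 0.06 and 0.08. Tnrc6b had a slope of -0.05 (adjusted p = 0.561). Pla2g2a, a secreted phospholipase, had 0.27 and was 2.61-fold above vehicle at 943 mg/kg (log2 1.38 ± 0.40), with 5 of 6 animals above the vehicle range. Ighl2 (0.12), Epha3 (0.15), Fthl17a (0.05), Eepd1 (0.06) and Fgf23 (0.05) followed with adjusted p from 0.783 to 0.825. At 943 mg/kg Epha3 differed from vehicle by 0.71, and its 2 other probe sets by 0.18 and 0.25. The vehicle signals of Epha3 (4.38), Fthl17a (3.20) and Fgf23 (2.74) lay below every array median. In limma, 0 probe sets passed the trend test and 0 the F test of the 6 groups (smallest adjusted p = 0.686), with 1762 and 1662 at an unadjusted p under 0.05, and the unmoderated model also gave 0 in both. The trend of Tekt4 passed when the values were quantile normalized again (adjusted p = 0.0407), without vehicle replicate 4 (0.0248) and without replicate 3 at 9.4 mg/kg (0.0428).

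Between the 2 highest doses, heat shock genes were lower at 943 than at 94.3 mg/kg in 13 of 16 members, with a median of -0.15. The chaperone Hsph1 differed by -0.52, Chordc1 by -0.30, the co-chaperone Stip1 by -0.29 and Ahsa1 by -0.15, and these 4 genes passed when adjusted over the list alone (smallest adjusted p = 0.00706). The list passed camera with the preset correlation (adjusted p = 1.25e-07, and adjusted p = 0.260 with an estimated correlation). The exact permutation of the 12 animals gave p = 0.00216, the smallest that 924 assignments allow, and 0.0628 after adjustment over the 29 lists, so that a lone list could not pass. Slc7a11 (-0.91, adjusted p = 0.0234, and -0.59 without replicate 5 at 94.3 mg/kg) and the p53 target Bbc3 (adjusted p = 0.0498) also passed when adjusted over the list alone. With 1 animal left out, 4 lists passed without replicate 2 at 943 mg/kg, 3 without replicate 1 at 94.3 mg/kg, and 2 without replicate 2 at 94.3 mg/kg or replicate 1 or 6 at 943 mg/kg. Over all probe sets 0 passed in limma and 0 in the unmoderated model, with 1768 at an unadjusted p under 0.05 (761 higher and 1007 lower). Without replicate 1 at 94.3 mg/kg, 18 probe sets passed, 2 higher (Bmf and Pdlim2) and 16 lower, the latter including Ctps1 (-0.64), Slc7a11 (-1.15) and Rrp12, Tsr1 and Nop56 (smallest adjusted p = 0.0274), all singled out after their values were seen except Slc7a11. Of 12 runs with 1 animal left out, this was the 1 with any call.

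The doses were last compared for shared differences. With 0 calls at each dose, 0 probe sets were shared between any 2 doses. The log2 differences of 2 doses correlated over all probe sets with r between 0.364 and 0.531. These values are across probe sets, which are not independent replicates. For 94.3 and 943 mg/kg the value was 0.531, where unchanged groups set against the same vehicle arrays gave a mean of 0.497 over 100 simulated draws (range 0.144 to 0.757). When 3 vehicle animals served 1 dose and the other 3 the other dose, the correlations lay between -0.130 and 0.0281.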

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

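The tests of whether the cholesterol list moves as one, of its dependence on dose, and of the ATF4 and ER stress response were chosen only after the result was seen, as were the exact permutation and the clock covariate.

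Chance could not be excluded for the number of probe sets at an unadjusted p under 0.05 in any comparison. Of 100 splits, 20 gave as many as the 1744 at 0.1 mg/kg (highest other 2619), 90 as many as the 1292 at 0.94 (2607), 62 as many as the 1506 at 9.4 (2913), 14 as many as the 2142 at 94.3 (3259) and 38 as many as the 1782 at 943 mg/kg (2997). Between 943 and 94.3 mg/kg 24 splits gave as many as the 1768 (3666). For the F test 30 regroupings of the 36 animals gave as many as the 1662 (2542), and for the trend 25 as many as the 1762 (2808).

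Chance could likewise not be excluded for the number of lists past camera with the preset correlation. Of 100 splits, 22 gave at least the 7 lists of 0.1 mg/kg (highest other 9), 28 the 6 of 0.94 (12), 23 the 7 of 9.4 (12), 25 the 6 of 94.3 (11), 94 the 1 of 943 mg/kg (12) and 96 the 1 between the highest doses (10). The median number of lists in the other splits was 4, 4, 5, 4, 4 and 3 in this order.

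Cholesterol synthesis genes were higher at 943 mg/kg (camera p = 4.68e-09 before adjustment, adjusted p = 0.819 with an estimated correlation, and exact permutation p = 0.126 for the list mean). With the first principal component of the clock genes in the model, 117% of the mean shift was kept. The share was 106% to 130% when 1 animal was left out. Within groups that component had only r = -0.219 with the list mean, so it could take up little of a shift. This cannot decide whether time of day at necropsy was the cause. The clock list itself was lower at both top doses against the same vehicle arrays (means -0.10 at 94.3 and -0.08 at 943 mg/kg) and had a slope over dose rank of -0.02 (permutation p = 0.0247, adjusted p = 0.431), so that a difference in clock phase between the groups is not excluded. Chance is open, since 21 of 100 splits gave a p as small (smallest other 2.88e-21). These genes do move together from animal to animal within groups, with a correlation of 0.687 estimated by camera. Whether this alone makes the shift is open, since camera with that correlation gave p = 0.0982. Dose also remains open and cannot be told apart from these, because the slope of the list mean over dose rank had a permutation p = 0.0297 but an adjusted p of 0.431 over the 29 lists, and the list was picked for its high values at the top doses.

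Cyp1a1 was higher at 943 mg/kg at a low signal. The 2619 probe sets within 0.25 log2 of its mean level had a median difference of 0.0116. Quantile normalization holds such a median near 0, so this cannot decide whether dim probe sets drifted. A single deviating animal is argued against, since the smallest difference with 1 animal left out was 0.28. An aryl hydrocarbon receptor response stays open and cannot be told apart from chance at 1 gene: the 7 other targets gave p = 0.805 in camera and an exact permutation p = 0.831, with a mean shift of 0.01 (95% interval -0.07 to 0.08). The prediction that such a p would exclude it was too strict, because a p that misses the threshold leaves small shifts possible and the interval of Cyp1a2 reaches 0.22.

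Psat1, Phgdh and Asns of the ER stress and ATF4 list and Slc7a11 of the NRF2 list (a low signal, 3.59 in vehicle), brought together only after their values were seen, lay above vehicle at 94.3 mg/kg without passing over all probe sets (adjusted p = 0.384 for Psat1 and Slc7a11), while 10 of the 25 members of the ER stress and ATF4 list were higher (adjusted p = 0.934 in camera, and exact permutation p = 0.494). A single deviating animal is argued against for Psat1, whose difference was at least 0.99 with any 1 animal left out. The lowest such differences were 0.71 for Phgdh, 0.83 for Asns and 0.71 for Slc7a11. That of Slc7a11 came without replicate 5 at 94.3 mg/kg, a group in which its SD was 0.99 beside 0.32 in vehicle. A general ATF4 and ER stress response stays open, because the list without Psat1 and Asns (23 genes, Phgdh among them) gave p = 0.173 in camera and an exact permutation p = 0.749, with a mean shift of -0.03 and a 95% interval from -0.21 to 0.16 that holds shifts of either sign. It cannot be told apart from a change limited to these genes, and the prediction that this p would exclude it was too strict for the same reason as for Cyp1a1. Chance is open too, since no split of the animals was run on these genes. The 14 of 100 splits with as many probe sets at an unadjusted p under 0.05 at this dose concern all probe sets, not these genes.

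In 20 of 282 groups of 6 animals, 1 animal lay far from the other 5, beside 14.1 that chance gives at about 1 in 20 groups. Of the 20, 13 concern list means and 7 concern genes. All values are log2.

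The aryl hydrocarbon receptor list mean was high in vehicle replicate 1 (6.55), as was the NRF2 list mean (8.34), while the NRF2 list mean was low in replicate 2 at 0.94 mg/kg (7.97). The bile acid list mean was high in replicate 5 at 9.4 mg/kg (9.99). The acute phase list mean was high in replicate 1 at 9.4 mg/kg (11.71) and in replicate 5 at 94.3 mg/kg (11.42). Male-predominant genes were low in vehicle replicate 5 (11.77), and female-predominant genes were high in replicate 4 at 0.1 mg/kg (6.94). The cholangiocyte list mean was high in replicate 6 at 943 mg/kg (6.21). Neutrophil markers were high in replicate 4 at 0.94 mg/kg (3.96), in replicate 1 at 9.4 mg/kg (4.78, next 3.88) and in replicate 6 at 94.3 mg/kg (4.21). Erythroid markers were low in vehicle replicate 4 (6.97).

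Siva1 was high in replicate 4 at 9.4 mg/kg (7.09), Ddx31 in vehicle replicate 2 (5.51), Ighl2 in vehicle replicate 2 (5.72) and Ugt2b1 in vehicle replicate 1 (12.18). Otub2 was low in replicate 1 at 94.3 mg/kg (6.63), Cyp3a2 in vehicle replicate 5 (13.35) and Pla2g2a in replicate 3 at 943 mg/kg (5.09, next 7.02).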

How the results depend on the processing

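The exact permutation, the clock covariate and leaving out animals for single values were tests chosen only after the result was seen. The number of probe sets past the threshold was 0 at each dose, between the highest doses and in the F test under every alternative that kept all animals or left out the array of lowest median correlation. For the trend it was 1 with quantile normalization again and 0 to 1 with 1 animal left out. With 1 animal left out it was 0 to 1 at 9.4 mg/kg, 0 to 11 at 94.3 mg/kg, 0 to 18 between the highest doses and 0 at the other doses. The animals behind the highest counts were replicate 3 at 9.4 mg/kg and replicate 1 at 94.3 mg/kg, and for the trend vehicle replicate 4 or replicate 3 at 9.4 mg/kg. The cause was not tested.

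The number of lists was 0 in all 6 comparisons with the estimated correlation and with fry. It was also 0 with the exact permutation, where a lone list cannot pass because the smallest possible p, 0.00216, becomes 0.0628 over the 29 lists, so this 0 says little against the lists. At 943 mg/kg it was 2 with rank-based camera. Between the highest doses it was 3 with the probe set of largest variance, 2 with rank-based camera and 2 with the replicate block. With 1 animal left out it was 2 to 8 at 0.1 mg/kg, 1 to 9 at 0.94, 2 to 8 at 9.4, 3 to 7 at 94.3, 1 to 7 at 943 and 1 to 4 between the highest doses. The lowest counts came without vehicle replicates 3 or 4 or replicates 4 or 6 at 0.1 mg/kg (2), without vehicle replicates 2, 3, 4 or 6 or replicate 2 at 0.94 mg/kg (1), without vehicle replicate 1 or replicate 4 at 9.4 mg/kg (2), and without vehicle replicate 3 or replicate 3 at 94.3 mg/kg (3). The highest count at 943 mg/kg came without vehicle replicate 5 (7), and between the highest doses without replicate 2 at 943 mg/kg (4). With 1 of the 12 animals left out, the cholesterol list at 94.3 and 943 mg/kg, the heat shock list between the highest doses and the urea cycle list at 0.1 mg/kg passed camera in all 12 runs, and each other list that had passed did so in 3 to 11 of 12. The cholesterol synthesis list had adjusted p = 0.436, 0.383 and 0.455 at 94.3 mg/kg and 0.819, 0.784 and 0.803 at 943 mg/kg with the estimated correlation, fry and the exact permutation. With 1 animal left out its adjusted p was 2.01e-11 to 0.00503 at 94.3 and 2.43e-14 to 0.00371 at 943 mg/kg. The cause was not tested.

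Values near 0 changed sign without passing any test. Dio1 at 943 mg/kg was 0.0114 with array weights and 0.0129 with quantile normalization again. Without the array of lowest median correlation, vehicle replicate 1, Dio1 was 0.00984 and Mdm2 0.00877. With 1 animal left out, Cyp7a1 was -0.401 to 0.0746, Dio1 -0.0628 to 0.0424, Mdm2 -0.139 to 0.00877, Mki67 -0.0177 to 0.189 and Por -0.0517 to 0.145. Every other named gene that was followed through the alternatives kept its sign. Not all named genes were followed. Sds, Hsph1 and Sesn1 at 943 mg/kg and the heat shock genes named between the highest doses were among those left out. Of the genes followed, those that came to pass with 1 animal left out or with quantile normalization again are Tekt4, Cep135, Limk2, Otub2, Psph and Slc7a11. The cause was not tested. Same-number animals of different groups did not pair: 90 such pairs had a mean r of 0.0154 (-0.266 to 0.292) beside -0.0030 for other pairs, 18 pairs were over 0.1, and 8 of 36 animals had their best match at their own number. With the replicate block the count of probe sets was 0 in all 8 tests. Dim probe sets near the array background cannot show small changes, and the differences found here are small.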

Other observations

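All comparisons of this part were chosen only after the values were seen.

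The mean of the 17 interferon response genes divided the 36 animals into 2 separate ranges with a gap of 0.31 log2. It lay between 5.64 and 6.14 in 12 animals and between 6.45 and 7.24 in 24 animals, a 3.04-fold span over all animals. The lower range held 2 animals of the vehicle group, 3 at 0.1 mg/kg, 3 at 0.94, 0 at 9.4, 1 at 94.3 and 3 at 943 mg/kg (Fisher's exact test, two-sided, p = 0.321). Kupffer cell and macrophage markers followed the same division, with means between 7.55 and 7.84 in the 12 animals and between 8.05 and 8.42 in the 24. Because the animals form 2 sets, no pooled correlation is given. Within the upper set the list means correlated with Pearson's r = 0.740 (permutation p = 8.0e-05, adjusted over 2 sets 0.00016) and Spearman's rho = 0.707 (p = 0.00019, adjusted 0.00038), and r was 0.689 without the 2 animals farthest from the median. Within the lower set r was 0.292 (permutation p = 0.365, adjusted 0.365) and rho 0.231 (p = 0.471, adjusted 0.471), with r = 0.272 without the 2 farthest.

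For 6 probe sets the animals split into high and low values more than 2 log2 apart with at least 2 animals on each side, and 3 named genes were among them. Ugt2b, a glucuronosyltransferase, was at 4.71 in replicate 1 at 0.1 mg/kg and 5.08 in replicate 1 at 943 mg/kg, beside 12.14 to 12.87 in the other 34 animals, and a second probe set had 1.86 and 2.58 beside 8.03 to 9.59. Abhd3 was high in 8 animals (mean 7.19) and low in 28 (mean 2.60) on 1 probe set, while a second probe set showed no such split (2.47 to 3.58 over the 36 animals). Ephx2, the soluble epoxide hydrolase, was high in 7 animals (mean 8.72) and low in 29 (mean 5.34), and 4 of the 7 were at 943 mg/kg, with 1 each in vehicle, 0.1 and 0.94 mg/kg. Its group counts gave Fisher's exact p = 0.0629 (adjusted over the 6 probe sets 0.378), and its difference at 943 mg/kg was 1.84 ± 0.63 in limma with an adjusted p of 0.865. Whether these genes carry inherited differences among the animals was not tested.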
